A study of Homo sapiens with 6 samples.

How the data were processed

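RNA from MDA-MB-231 cells was sequenced in 6 libraries, 3 from cells treated with AGEs (100 µg/ml for 72 h) and 3 from cells treated with BSA under the same conditions. The groups and replicate numbers were taken from the sample titles. The authors deposited one table with FPKM per gene and library, per the file headers, and a second table with FPKM, a log2 fold change, a linear fold ratio, a p-value and a q-value for each gene they listed as higher with AGEs. HISAT2 2.1.0 and StringTie 1.3.3 are named in the submitters' processing notes, without their settings, and so are the genome builds GRCm38, mm10 and hg19. The gene identifiers are human, and the strand setting, the annotation release and the filter that led to the listed genes are not given in the sources used here. The columns headed as group FPKM in the deposited list of higher genes hold, as recomputed from the same file, group means of log2(FPKM + 1). Its log2 fold changes equal differences of these means and its p-values equal an equal-variance test of 3 against 3 libraries. The gene table also held 3 columns of values that match none of the samples of this study, which were not used.

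The gene table held 11986 genes, all annotated as protein coding, with 6 symbols on 2 rows each. MMP9 was not analysed here. FPKM hold no read numbers. The low values of 1058 genes with a mean under 1 FPKM were examined for steps of whole reads between a pair of libraries, and at most 14 of them fell within a 0.5% window of one ratio, so the depth is unknown and no test on counts was run. The precision therefore rests on the spread between the 3 libraries of a group.

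Genes with at least 0.5 FPKM in at least 3 of the 6 libraries were tested (11737 genes) on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using a model with the treatment alone, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. The same steps, run on simulated values for 11737 genes with the spread of these libraries, recovered 59.7% of genes changed by 0.5 on the log2 scale, 80.6% of those changed by 1 and 93.9% of those changed by 2, with 12 false calls among 168. The simulated genes varied independently of each other, and more were called than the 26 in the real libraries, which loosens the adjusted threshold. These shares therefore check the steps and do not give the power in the real libraries. A set of 21 gene lists had been fixed before the data were examined, and 20 of them had the 5 tested members required for a list test. They were tested with limma's camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the lists. An estimated correlation and fry, which tests whether the genes of a list move one way on balance, were alternatives. The members of each list were also adjusted over the list alone. Changes of old and new gene symbols were matched by hand.

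The genes named in the text followed a rule fixed before the data were examined. It took MMP9, AGER, LGALS3, DNMT1, DNMT3A, DNMT3B, TET1, TET2, TET3 and SP1 in any case. It took up to 10 higher and 10 lower genes with the largest absolute log2 fold changes among those past the threshold, with a proper symbol, group values that did not overlap and a mean of at least 1 FPKM. From each list it took up to 4 members past the threshold by size of change, or the 2 with the smallest p where none had passed, and it added up to 3 further called genes per direction with the highest mean. Other genes are marked as chosen after their values were seen. Some genes that the rule took are not reported here.

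Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or 1 FPKM), centring on library medians, quantile normalization, moderation without a trend or robust, array quality weights, the replicate number as a block, a threshold that also required an absolute log2 fold change of 1, and leaving out each library in turn. Further alternatives were added after seeing the data, namely the rule behind the authors' deposited list, leaving out genes that overlap another listed gene on the same strand, a correction for transcript GC content and length, and leaving out genes held by a second list. GC content, length and the share of genes that overlap another annotated gene came from the GENCODE 29 annotation, matched by gene identifier for 11916 genes (99.4%). Its coordinates served only to find those overlaps within that annotation and are not printed. Overlaps between listed genes (1004 genes on the same strand) came from the positions in the gene table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 served for tables and checks.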

Results

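Gene expression was measured by RNA sequencing in MDA-MB-231 cells, an established human triple-negative breast cancer cell line with mesenchymal features. The cells had been exposed for 72 h to 100 µg/ml of either advanced glycation end products (AGEs), which are proteins modified by sugars, or bovine serum albumin (BSA), the unmodified protein used as control. Each treatment had 3 libraries, called AGEs replicates 1 to 3 and Con replicates 1 to 3. The deposited table gave FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) for 11986 protein-coding genes. FPKM summed over the listed genes lay between 194161 and 199706 per library and the median gene had between 6.19 and 6.34 FPKM. The number of reads behind these values is unknown, so no counting error can be given. Pearson correlations across genes of log2(FPKM + 1) were 0.981 to 0.987 between libraries of one treatment and 0.976 to 0.983 between treatments. AGEs replicate 3 stood nearer to the controls than the other AGEs libraries did. It correlated at 0.9832, 0.9827 and 0.9817 with Con replicates 1, 2 and 3. With AGEs replicates 1 and 2 it correlated at 0.9807 and 0.9831, so each control was closer to it than AGEs replicate 1. On the first principal component, which held 35.6% of the variance, AGEs replicate 3 scored -0.22. AGEs replicates 1 and 2 scored -17.3 and -13.8, and the controls 5.45 to 13.7.

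The main question was which genes differed between AGEs-treated and BSA-treated cells. Chemokine and cytokine genes were among those with the largest rises. CXCL8, which encodes the neutrophil chemoattractant interleukin-8, stood at 63.7 ± 14.6 FPKM (SD, n = 3) with AGEs and at 12.5 ± 2.40 FPKM (SD, n = 3) with BSA, a log2 fold change of 2.25 ± 0.21 (SE, limma adjusted p = 0.0275). CSF2, which encodes the myeloid growth factor GM-CSF, rose from 2.61 ± 0.321 to 13.9 ± 4.11 FPKM (log2 fold change 2.02 ± 0.19, adjusted p = 0.0293). The chemokine gene CXCL2 rose from 1.05 ± 0.322 to 4.79 ± 0.718 FPKM (log2 fold change 1.499 ± 0.15, adjusted p = 0.0293). DAG1, the gene of the extracellular matrix receptor dystroglycan, had the largest rise among the called genes, from 1.74 ± 0.330 to 16.4 ± 5.30 FPKM (log2 fold change 2.62 ± 0.25, adjusted p = 0.0275).

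Other called genes encode regulators of stress responses, RNA decay and the cytoskeleton. NFE2L2, which encodes the oxidative stress transcription factor NRF2, rose from 6.002 ± 0.422 to 16.9 ± 2.35 FPKM (log2 fold change 1.35 ± 0.11, adjusted p = 0.0146). ATF3, a stress-induced transcription factor gene, rose by 1.75 ± 0.20 on the log2 scale (adjusted p = 0.0487), and GADD45A, a growth arrest and DNA damage gene, by 0.98 ± 0.07 (adjusted p = 0.0115). The FPKM of ATF3 and GADD45A stand under each other's name in the authors' deposited table of higher genes, so which of these values belongs to which gene is open, although both sets of values passed. DCP2, the gene of an mRNA decapping enzyme, rose by 1.35 ± 0.08 (adjusted p = 0.00515). PDLIM5, which encodes a PDZ and LIM domain scaffold protein, rose by 1.16 ± 0.06 (adjusted p = 0.00177). FAM217B and KIAA1191 rose by 1.35 ± 0.08 and 0.99 ± 0.04 (adjusted p = 0.00495 and 0.00146). The other higher genes were TNFAIP3, NFKBIA and IFIT2, which are described with their groups below, and PIGV, IL10RB, MTRR, MAU2 and AEN, which fall outside the rule for named genes and were listed after their values were seen. The log2 fold changes of these last genes lay between 0.42 and 0.87, and the locus of IL10RB overlaps the readthrough gene AP000295.1. In the reference annotation NFE2L2, IFIT2 and DPYSL2 also overlap another gene on the same strand.

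Fewer genes fell. DPYSL2, which encodes a collapsin response mediator protein that binds tubulin, had the smallest unadjusted p of all genes and fell from 27.8 ± 0.428 to 14.7 ± 0.0506 FPKM (log2 fold change -0.88 ± 0.03, adjusted p = 0.00146). TMEM30A, the gene of the subunit shared by phospholipid flippases, fell from 41.4 ± 0.546 to 24.1 ± 0.602 FPKM (log2 fold change -0.76 ± 0.04, adjusted p = 0.00177). The actin-binding protein gene AIF1L fell from 2.98 ± 0.282 to 1.18 ± 0.236 FPKM (log2 fold change -0.87 ± 0.10, adjusted p = 0.0487). TNFRSF10D, which encodes a decoy receptor for the death ligand TRAIL, and DDX17, an RNA helicase gene, had log2 fold changes of -0.62 ± 0.07 and -0.38 ± 0.04 (both adjusted p = 0.0487). The clone-named genes Z83844.1 and AC093525.2 also passed, and their loci overlap NOL12 and TRIOBP, and TBC1D24 and ATP6V0C, so the division of reads between these genes is uncertain. Z83844.1 had 0.0715, 0 and 0.0494 FPKM in AGEs replicates 1 to 3 and 1.19, 0.940 and 0.993 FPKM in Con replicates 1 to 3. AC093525.2 was listed at 0 in all 3 AGEs libraries and at 0.616, 0.647 and 0.519 FPKM in the controls.

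In all, 26 of 11737 tested genes passed a limma adjusted p of 0.05, 19 of them higher and 7 lower with AGEs. At an unadjusted p under 0.05 there were 2062 genes, 1069 higher and 993 lower, where chance alone would give 587 on average. How far such a count varies when genes move together was not tested, so the difference has no p-value. Fold changes are differences of mean log2(FPKM + 1), which understate changes of genes with low FPKM, and the median over all tested genes was -0.0018. The labels do not say that the 3 libraries of a treatment came from separate cultures, so p-values measure the spread between these samples, which may be technical. The count was 396 without AGEs replicate 3, and 16, 14 and 15 without AGEs replicate 1, AGEs replicate 2 and Con replicate 1. The calls of IFIT2 and AIF1L ended in 15 of 18 alternatives, those of ATF3 and NFKBIA in 13, and those of DDX17, TNFRSF10D and MAU2 in 12. Those of CXCL8, NFE2L2 and GADD45A ended in 4, those of DAG1 and CSF2 in 5, and those of CXCL2 and TNFAIP3 in 6. The counts of ATF3 and GADD45A would trade places if their names were exchanged. The count was 17 when genes needed 1 FPKM to be tested and 168 with array quality weights.

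**Figure D1:**
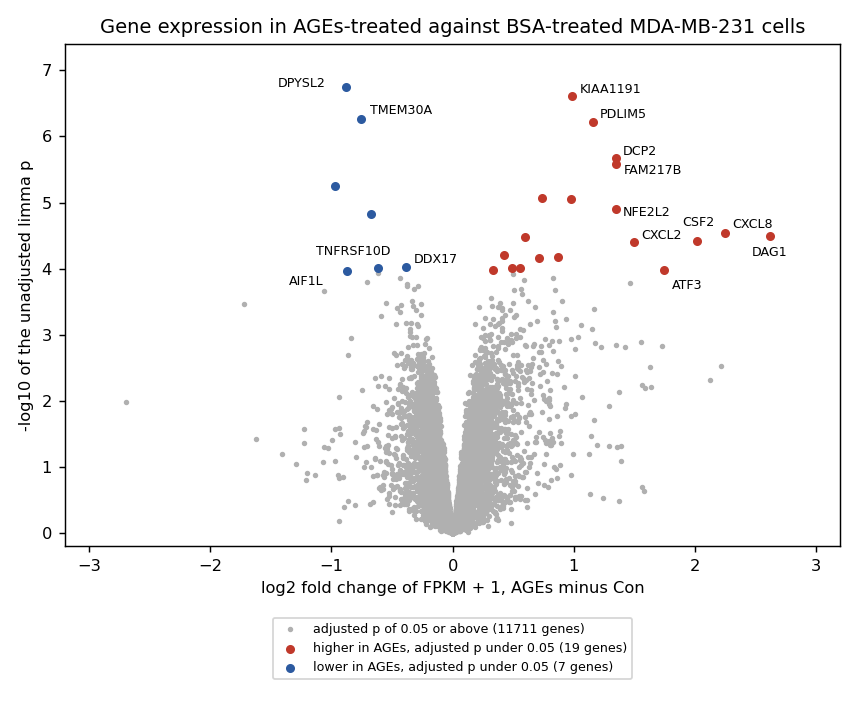
Each point is 1 of the 11737 tested genes, with the log2 fold change of FPKM + 1 (AGEs minus Con, 3 libraries each) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 19 higher and 7 lower genes with an adjusted p under 0.05 are coloured, DAG1 at 2.62 and CXCL8 at 2.25 lie farthest to the right, and DPYSL2 has the smallest p.

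In the deposited gene table, these genes lie at the following positions. The builds hg19, mm10 and GRCm38 are named in the submitters' processing notes, of which hg19 is the human one, and the positions are taken to be on it. CXCL8 (ENSG00000169429.10_2) spans chromosome 4 from 74606223 to 74609433, near CXCL2 (ENSG00000081041.8_2) at 74962752 to 74965010 on the same chromosome. CSF2 (ENSG00000164400.5_2) spans chromosome 5 from 131409483 to 131411863, DAG1 (ENSG00000173402.11_3) chromosome 3 from 49506136 to 49573051, and NFE2L2 (ENSG00000116044.15_3) chromosome 2 from 178092323 to 178257425. DPYSL2 (ENSG00000092964.17_4) spans chromosome 8 from 26371538 to 26515694, and TMEM30A (ENSG00000112697.15_2) chromosome 6 from 75962640 to 75994684. The values are for whole genes and do not separate exons or transcripts.

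The study's title concerns demethylation of the MMP9 promoter. MMP9, which encodes the secreted gelatinase, was not analysed here. Among the matrix metalloproteinases and other pericellular proteases, 0 of 20 tested genes passed over all genes by limma, with 3 higher and 2 lower at an unadjusted p under 0.05, and 2 higher and 1 lower when adjusted over the list alone. PLAU, the urokinase gene, stood at 131 ± 9.54 FPKM with AGEs and 96.6 ± 4.80 FPKM with BSA (log2 fold change 0.43 ± 0.07, adjusted p = 0.0869), and did not pass. The metalloproteinase inhibitor gene TIMP3 had a log2 fold change of -0.21 ± 0.05 (adjusted p = 0.1495). MMP14, a membrane-bound metalloproteinase gene chosen after its values were seen, had a log2 fold change of -0.16 ± 0.09 (adjusted p = 0.440). The median log2 fold change of the list was 0.05 (camera adjusted p = 0.704).

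The genes of DNA methylation and demethylation showed no common direction. Of 23 tested members GADD45A alone passed over all genes, and also when adjusted over the list alone. Whether its values belong to it or to ATF3 is open, as described above. With these names exchanged, the GADD45A call would be the one that 13 of 18 alternatives ended. DNMT1, the maintenance methyltransferase gene, had 27.7 ± 1.40 FPKM with AGEs and 27.3 ± 0.282 FPKM with BSA (log2 fold change 0.02 ± 0.05, adjusted p = 0.876). The de novo methyltransferase genes DNMT3A and DNMT3B had log2 fold changes of -0.03 ± 0.16 and 0.07 ± 0.13 (adjusted p = 0.934 and 0.797). The demethylating dioxygenase genes TET1, TET2 and TET3 had log2 fold changes of -0.16 ± 0.07, -0.10 ± 0.12 and 0.08 ± 0.06 (adjusted p = 0.297, 0.714 and 0.531), and TET1 reached only 0.447 ± 0.106 FPKM with AGEs and 0.618 ± 0.0410 FPKM with BSA. SP1, a transcription factor gene, had a log2 fold change of 0.05 ± 0.08 (adjusted p = 0.760). The list as a whole did not pass (median -0.03, camera adjusted p = 0.884).

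The genes of AGE receptors and of the glyoxalase pathway, which detoxifies precursors of AGEs, did not pass either, with 0 of 12 tested members past the limma threshold over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and 1 was lower. AGER, the gene of the receptor RAGE, had low values of 1.03 ± 0.213 FPKM with AGEs and 0.942 ± 0.227 FPKM with BSA (log2 fold change 0.06 ± 0.12, adjusted p = 0.805). LGALS3, which encodes the AGE-binding lectin galectin-3, had 40.8 ± 0.744 and 38.2 ± 1.19 FPKM (log2 fold change 0.10 ± 0.04, adjusted p = 0.279). The list had a median of 0.07 (camera adjusted p = 0.927).

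The list of NF-kB target and cytokine genes was higher with AGEs, although 18 of its 23 members did not pass singly over all genes. All tested members had positive log2 fold changes, with a median of 0.60, and the list passed (camera adjusted p = 5.11e-20 at the preset correlation of 0.01, and adjusted p = 0.297 with an estimated correlation). Over all genes 5 members passed, namely CXCL8, CSF2, CXCL2, TNFAIP3 and NFKBIA, and 21 passed when adjusted over the list alone. TNFAIP3 and NFKBIA, which encode inhibitors of NF-kB signalling that are themselves induced by it, rose by 0.71 ± 0.08 and 0.49 ± 0.06 on the log2 scale (adjusted p = 0.0426 and 0.0487). Among members chosen after their values were seen, the chemokine gene CXCL1 and the interleukin-1 beta gene IL1B, had log2 fold changes of 1.46 ± 0.18 and 1.01 ± 0.19 (adjusted p = 0.0584 and 0.126). Relative to the mean of the controls, the median member lay 0.77, 0.60 and 0.44 higher in AGEs replicates 1, 2 and 3, so that the library nearest to the controls also had the lowest level.

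The joint list of unfolded protein response genes and targets of the stress transcription factor ATF4 was also higher with AGEs, and its parts were not tested apart. The median log2 fold change of the 26 members was 0.60 (camera adjusted p = 3.88e-09, and adjusted p = 0.297 with an estimated correlation). Of the 26 members, 22 had positive log2 fold changes, and 18 were higher and 2 lower at an unadjusted limma p under 0.05. The members named here are all among the positive ones. ATF3 passed over all genes, while 17 members passed as higher and 1 as lower when adjusted over the list alone. Members chosen after their values were seen included DDIT3, which encodes the pro-apoptotic factor CHOP, at 37.1 ± 5.97 FPKM with AGEs and 12.1 ± 5.62 FPKM with BSA (log2 fold change 1.63 ± 0.35, adjusted p = 0.140). The pseudokinase gene TRIB3, the stress sensor gene SESN2, the transcription factor gene CEBPB and the asparagine synthetase gene ASNS had log2 fold changes of 1.55 ± 0.28, 1.72 ± 0.32, 0.84 ± 0.11 and 0.77 ± 0.16 (adjusted p = 0.118, 0.121, 0.0625 and 0.140). Of the genes of the unfolded protein response, XBP1 had a log2 fold change of 0.90 ± 0.19 (adjusted p = 0.140) and HERPUD1, which acts in the degradation of misfolded proteins and was chosen after its values were seen, one of 0.63 ± 0.21 (adjusted p = 0.224), or of 0.37 without AGEs replicate 1. HSPA5, the gene of the main chaperone of the endoplasmic reticulum, also chosen after its values were seen, had a log2 fold change of 0.10 ± 0.04 (adjusted p = 0.320). The median member lay 0.79, 0.62 and 0.39 above the control mean in AGEs replicates 1, 2 and 3.

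**Figure D2:**
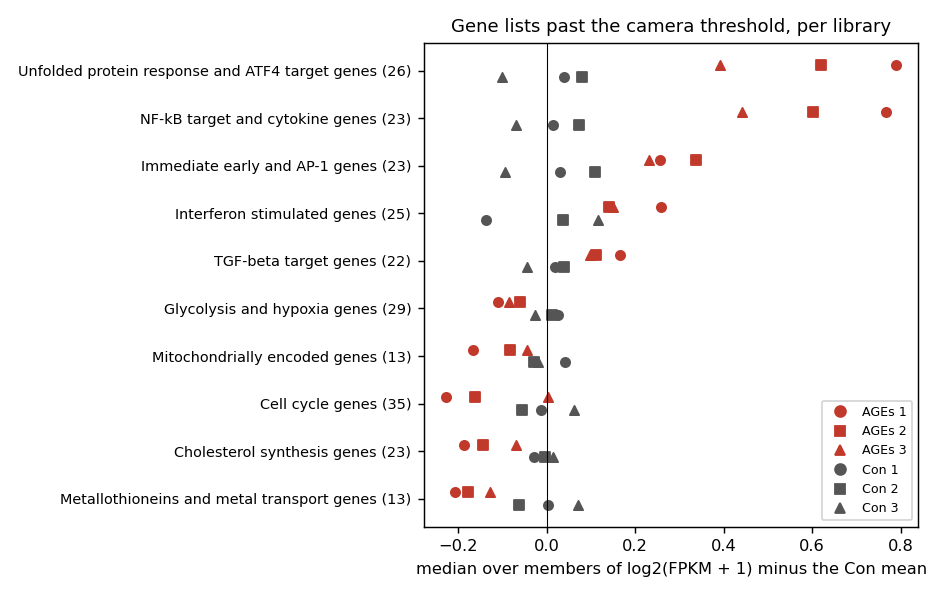
For each of the 10 gene lists past the camera threshold (number of tested members in brackets), the horizontal axis shows the median over its members of log2(FPKM + 1) minus the Con mean, with 1 point per library. The ATF4 list (0.79, 0.62 and 0.39 in AGEs replicates 1, 2 and 3) and the NF-kB list (0.77, 0.60 and 0.44) stand farthest from the controls, and AGEs replicate 3 is the lowest AGEs library in both.

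Immediate early and AP-1 genes, interferon-stimulated genes and TGF-beta target genes were higher as lists by smaller amounts. The immediate early list had a median log2 fold change of 0.25 over 23 members, 19 of them positive. Its camera adjusted p was 4.90e-06 at the preset correlation and 0.336 with an estimated correlation. By limma, ATF3 passed over all genes. At an unadjusted p under 0.05, 11 members were higher and 1 was lower, and 10 passed as higher when adjusted over the list alone. JUNB, an AP-1 subunit gene, had a log2 fold change of 0.90 ± 0.12 (adjusted p = 0.0792). EGR1 and DUSP1, an early growth response factor gene and a MAP kinase phosphatase gene, both chosen after their values were seen, had log2 fold changes of 2.21 ± 0.47 and 0.94 ± 0.15 (adjusted p = 0.140 and 0.0919). The interferon-stimulated list had a median of 0.19 over 25 members, 22 of them positive (camera adjusted p = 1.57e-05, and adjusted p = 0.355 with an estimated correlation). Its median member lay 0.26, 0.14 and 0.15 above the control mean in AGEs replicates 1, 2 and 3, but at -0.14, 0.04 and 0.12 in Con replicates 1, 2 and 3, so the controls differed among themselves by as much as the list's median. IFIT2, which encodes an interferon-induced RNA-binding protein, rose from 19.2 ± 0.192 to 24.4 ± 0.670 FPKM (log2 fold change 0.33 ± 0.04, adjusted p = 0.0487), a call that 15 of 18 alternatives ended (adjusted p from 0.0280 to 0.176), and 2 members passed when adjusted over the list alone. The cytosolic RNA sensor gene IFIH1, chosen after its values were seen, had a log2 fold change of 0.32 ± 0.07 (adjusted p = 0.140). The TGF-beta list had a median of 0.13 over 22 members, with 0 past the limma threshold over all genes, 7 higher and 4 lower at an unadjusted p under 0.05, and 6 higher and 2 lower when adjusted over the list alone. Its camera adjusted p was 0.0467, against adjusted p = 0.351 with an estimated correlation, and 8 of 20 alternatives ended the call, among them those without AGEs replicate 1 (0.0668), AGEs replicate 3 (0.0798) and Con replicate 3 (0.0976). CYR61, which encodes a secreted matricellular protein, had 329 ± 20.2 FPKM with AGEs and 274 ± 7.59 FPKM with BSA (log2 fold change 0.26 ± 0.05, adjusted p = 0.139).

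Several lists were lower. The list of metallothioneins, metal transport and heat shock genes had a median log2 fold change of -0.16 over 13 members (camera adjusted p = 6.71e-04, and adjusted p = 0.297 with an estimated correlation), with 0 past the limma threshold over all genes, 1 higher and 7 lower at an unadjusted p under 0.05, and 1 higher and 7 lower when adjusted over the list alone. Its lowest members were not metallothioneins but genes of cytosolic heat shock chaperones. HSPA1B had 17.3 ± 4.39 FPKM with AGEs and 59.8 ± 16.5 FPKM with BSA (log2 fold change -1.72 ± 0.24, adjusted p = 0.0792), and its cochaperone gene DNAJB1 had a log2 fold change of -0.55 ± 0.08 (adjusted p = 0.0792). HSPA1A and HSPA8, chosen after their values were seen, had log2 fold changes of -2.70 ± 0.74 and -0.87 ± 0.17 (adjusted p = 0.183 and 0.136). HSPA1A had 6.69, 8.75 and 0.364 FPKM in AGEs replicates 1, 2 and 3, and a log2 fold change of -1.81 without AGEs replicate 3 (adjusted p = 0.0313, past the threshold), the library with the highest AGEs values of HSPA1B and HSPA8. The metallothionein genes MT2A and MT1A, chosen in the same way, stood at 0.00 ± 0.04 and -0.26 ± 0.08 (adjusted p = 0.970 and 0.203), of which MT1A passed as lower when adjusted over the list alone. HSPA1A and HSPA1B are near-identical copies, so the division of reads between them is uncertain.

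Cell cycle genes had a median log2 fold change of -0.12 over 35 members (camera adjusted p = 1.56e-04, and adjusted p = 0.470 with an estimated correlation). By limma 0 members passed over all genes, with 1 higher and 8 lower at an unadjusted p under 0.05, and 1 higher and 1 lower when adjusted over the list alone. CDKN1A, which encodes the cell cycle inhibitor p21, had a log2 fold change of 0.70 ± 0.11 (adjusted p = 0.0949), CCND1, the cyclin D1 gene, one of -0.29 ± 0.06 (adjusted p = 0.140), and the proliferation marker gene MKI67, chosen after its values were seen, one of -0.31 ± 0.10 (adjusted p = 0.216). The median member lay at -0.23, -0.16 and 0.0037 relative to the control mean in AGEs replicates 1, 2 and 3, so AGEs replicate 3 was not lower. Cholesterol synthesis genes had a median of -0.13 over 23 members (camera adjusted p = 8.29e-04, and adjusted p = 0.341 with an estimated correlation), with 0 past the limma threshold over all genes, 2 higher and 6 lower at an unadjusted p under 0.05, and 1 higher and 3 lower when adjusted over the list alone. EBP, a sterol isomerase gene, had a log2 fold change of -0.37 ± 0.08 (adjusted p = 0.140). Glycolysis and hypoxia genes had a median of -0.07 over 29 members (camera adjusted p = 0.00162, and adjusted p = 0.297 with an estimated correlation), with 0 past the limma threshold over all genes or adjusted over the list alone, and 2 higher and 8 lower at an unadjusted p under 0.05. PFKFB3, a glycolytic regulator gene, had a log2 fold change of -0.24 ± 0.06 (adjusted p = 0.167), and the angiogenic factor gene VEGFA, chosen after its values were seen, one of 0.80 ± 0.22 (adjusted p = 0.183). All 13 mitochondrially encoded genes had negative log2 fold changes, with a median of -0.11 (camera adjusted p = 5.07e-05, and adjusted p = 0.355 with an estimated correlation). Of these, 0 passed by limma over all genes, 0 were higher and 4 lower at an unadjusted p under 0.05, and 1 passed when adjusted over the list alone. MT-ND6, the member encoded on the opposite strand from the others, had 298 ± 5.55 FPKM with AGEs and 388 ± 21.7 FPKM with BSA (log2 fold change -0.38 ± 0.05, adjusted p = 0.0604). Quantile normalization, which gives every library the same distribution of values, ended this call (camera adjusted p = 0.961). With that exception, the estimated correlation gave the highest adjusted p over the 20 alternatives for each of the lists that passed, none of which passed with it.

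**Figure D3:**
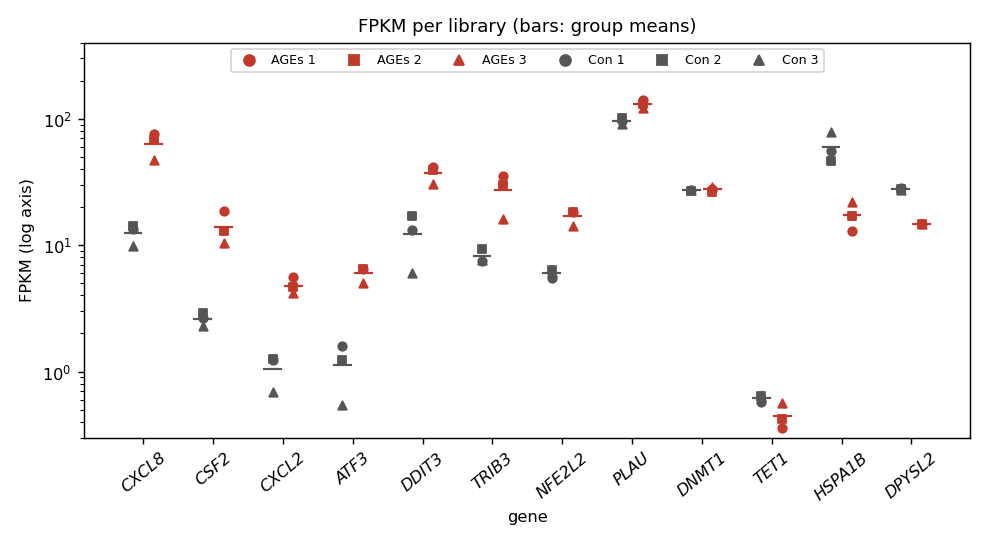
Each point is the FPKM of 1 gene in 1 library on a log axis, with AGEs libraries in red, Con libraries in grey and bars at the group means (n = 3 each). CXCL8 (63.7 against 12.5 FPKM), CSF2, CXCL2, ATF3 and NFE2L2 passed as higher and DPYSL2 (14.7 against 27.8 FPKM) as lower, while DDIT3, TRIB3, PLAU, DNMT1, TET1 and HSPA1B did not pass over all genes.

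The remaining lists did not pass. NRF2 target and oxidative stress genes had a median log2 fold change of 0.0069 over 23 members (camera adjusted p = 0.979) although NFE2L2 itself rose, with 0 past the limma threshold over all genes, 1 higher and 1 lower at an unadjusted p under 0.05, and 1 higher when adjusted over the list alone. SLC7A11, the cystine transporter gene and also a target of ATF4, had a log2 fold change of 0.76 ± 0.13 (adjusted p = 0.116), while the classical NRF2 targets NQO1 and HMOX1, chosen after their values were seen, had log2 fold changes of -0.02 ± 0.08 and 0.04 ± 0.09 (adjusted p = 0.938 and 0.852). Mesenchymal genes and factors of epithelial-mesenchymal transition had a median of -0.0085 over 21 members (camera adjusted p = 0.884), among them SPARC at -0.22 ± 0.04 (adjusted p = 0.116) and VIM, chosen after its values were seen, at -0.09 ± 0.08 (adjusted p = 0.579). Epithelial genes had a median of -0.07 over 17 members (camera adjusted p = 0.339), with the keratin gene KRT19 at -0.27 ± 0.06 and the claudin gene CLDN1 at 0.54 ± 0.12 (both adjusted p = 0.140). The medians of the lysosome, replication-dependent histone and cytosolic ribosomal protein lists were 0.03, -0.04 and -0.02 (camera adjusted p = 0.256, 0.884 and 0.836). Markers of other breast cell types had a median of -0.10 over 10 members (camera adjusted p = 0.391), with members in both directions. XBP1, a transcription factor gene of luminal cells and of the unfolded protein response, had a log2 fold change of 0.90 ± 0.19 (adjusted p = 0.140) and the luminal gene AGR2 one of -0.29 ± 0.05 (adjusted p = 0.121), while TFF3 and GATA3, chosen after their values were seen, stood at 0.31 ± 0.10 and 0.26 ± 0.10 (adjusted p = 0.199 and 0.257). Of the fibroblast, endothelial and leukocyte markers only CD68 and PDGFRB reached the expression filter, at log2 fold changes of 0.22 ± 0.07 and 0.14 ± 0.11 (adjusted p = 0.208 and 0.556), too few for a list test. By limma, 0 members of the mesenchymal, epithelial, lysosome, histone, ribosomal protein and other breast cell type lists passed over all genes, while 2, 2, 2, 0, 2 and 3 were higher and 3, 2, 0, 0, 0 and 4 were lower at an unadjusted p under 0.05. When adjusted over the list alone, 0, 1, 0, 0, 0 and 2 were higher and 1, 1, 0, 0, 0 and 3 were lower in the same order. For the DNA methylation, mesenchymal, other breast cell type, histone and ribosomal protein lists, the median and the camera direction were lower while the mean was above 0, at 0.0037, 0.0091, 0.02, 0.0066 and 5.28e-04.

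The authors' deposited table of genes higher with AGEs held 100 genes, chosen on these same libraries and so no independent evidence of their direction. Its folds reached from 1.503 to 6.15, the last for DAG1, its unadjusted p-values reached 0.0482, and its q-values lay between 0.0270 and 0.338, with 2 genes under 0.05. All 100 genes, and no others, were recovered from the deposited FPKM by an equal-variance test on log2(FPKM + 1) with an unadjusted p under 0.05 and at least 1.5-fold, and the same rule gave 21 lower genes. Of the 100 genes, 15 passed the limma adjusted p of 0.05, and these were 15 of the 19 genes called higher.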

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

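Depth is unknown, so the limits come from 3 libraries per treatment, and the alternatives with the authors' rule, without overlapping genes, with the GC and length correction and without genes of a second list were chosen after seeing the data. The cause of the changes between settings was not tested, and some settings test fewer genes or libraries. Of the 26 called genes, 17 were called with the stricter filter (2 of them lower), with 4 lower genes at pseudocounts of 0.1 and 0.5 and with no filter. Array weights gave 168 genes (122 higher, 46 lower), all 26 among them. A required absolute log2 fold change of 1 left 9 genes, 9 higher and 0 lower, and the authors' rule gave 121 genes, 100 higher and 21 lower. Leaving out 1 library gave 14 to 396 genes, with 8 to 256 higher and 5 to 140 lower. The 396 genes came without AGEs replicate 3 and held all 26, while 7 to 16 of the 26 were called without any one of the other libraries. Median centring, quantile normalization, no trend, robust moderation, no overlapping genes and the GC and length correction gave 19 to 30 genes.

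With the replicate number as a block, 1 gene was called, 1 higher and 0 lower. The same-numbered samples' deviations correlated at -0.111, 0.059 and 0.05, and not every sample correlated best with its own number, so the numbers were not taken to pair the samples. The block ended 25 of the 26 calls. It also leaves fewer residual degrees of freedom, so the lost calls do not by themselves show an effect of the replicate number. With the block, 2148 genes had an unadjusted limma p under 0.05, against 2062 in the main analysis.

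Of the 26 called genes, 0 changed direction in 463 values under alternatives and 159 values no longer passed. DPYSL2, KIAA1191, TMEM30A, PDLIM5, FAM217B, DCP2 and Z83844.1 lost the call under the block alone. CXCL8, NFE2L2 and GADD45A lost it in 4 of 18 alternatives, DAG1 and CSF2 in 5, and CXCL2 and TNFAIP3 in 6. IFIT2 and AIF1L lost it in 15 of 18 alternatives, ATF3 and NFKBIA in 13, and DDX17, TNFRSF10D and MAU2 in 12. Among 77 followed genes without a call, 54 values passed under an alternative. The 5 higher and 5 lower lists became 0 and 0 with an estimated correlation, and 1 higher (NF-kB) and 0 lower with fry. The TGF-beta list lost its call in 8 of 20 alternatives and the mitochondrial list in 3, among them quantile normalization, and 0 of the 10 called lists changed direction.

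Lists and genes without a call changed direction as follows. For lists, the direction is that of the list test, and the value in brackets is the median under that setting. Apart from leaving out libraries, the median itself changed sign in only some of the cases named here. These were mesenchymal genes under array weights, NRF2 targets under median centring, ribosomal genes under the GC and length correction, and proteases without genes of a second list. Under array weights the camera direction turned for the lists of AGE receptors (median 0.047), mesenchymal genes (0.013) and NRF2 targets (0.0039), and the estimate for DNMT1 (-0.011) and MT2A (-0.0044). Median centring turned NRF2 targets (-0.010), DNMT1 (-0.000385) and MT2A (-0.013), and quantile normalization ribosomal genes (-0.010) and MT2A (-0.048). The NRF2 list also turned under the replicate block (0.0069) and the GC and length correction (0.0061), which turned ribosomal genes too (0.000471). Histone genes turned with the stricter filter (-0.0074), DNA methylation genes with fry (-0.034), and the protease list without genes of a second list (-0.079). Leaving out each library in turn moved the medians from -0.054 to 0.028 for DNA methylation, from -0.012 to 0.056 for AGE receptors, from -0.0090 to 0.070 for proteases, from -0.034 to 0.056 for mesenchymal genes, from -0.0075 to 0.019 for NRF2 targets, from -0.095 to 0.0010 for histones and from -0.045 to 0.0059 for ribosomal genes. It moved the log2 fold changes from -0.031 to 0.14 for AGER, from -0.019 to 0.051 for DNMT1, from -0.15 to 0.10 for DNMT3A, from -0.057 to 0.14 for DNMT3B, from -0.17 to 0.039 for TET2, from -0.031 to 0.096 for SP1, from -0.020 to 0.023 for MT2A, from -0.034 to 0.14 for HMOX1, from -0.012 to 0.063 for TGFA and from -0.089 to 0.056 for NQO1. A test on recovered reads was not run, because no whole-read steps were seen in the pair of libraries examined. That check used low genes of AGEs replicate 1 and Con replicate 1 only. Its ability to find steps was not measured, so it cannot exclude steps in this pair or elsewhere. MMP9 was not analysed here under any setting.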

Other observations

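The genes in this paragraph were picked after their values were seen, so their common directions are no test of a group, and they did not pass the limma adjusted p over all genes. The tests on overlapping genes and on the exchanged values were also chosen after seeing the data. SLC38A2, which encodes a neutral amino acid transporter, stood at 186 FPKM with AGEs and 103 FPKM with BSA (log2 fold change 0.86 ± 0.14, SE, adjusted p = 0.0993), and SLC7A5, which encodes the light chain of a leucine transporter and is also a member of the ATF4 list, had a log2 fold change of 0.73 ± 0.14 (adjusted p = 0.133). The cystathionine gamma-lyase gene CTH stood at 12.9 FPKM with AGEs and 4.12 FPKM with BSA (log2 fold change 1.42 ± 0.26, adjusted p = 0.121), and the mitochondrial folate enzyme gene MTHFD2 had a log2 fold change of 0.65 ± 0.17 (adjusted p = 0.178). Of genes of ligands of the EGF receptor, AREG had a log2 fold change of 0.93 ± 0.27 (adjusted p = 0.186), EREG one of 0.71 ± 0.15 (adjusted p = 0.140) and HBEGF one of 0.68 ± 0.10 (adjusted p = 0.0796), while TGFA and BTC stood at 0.02 ± 0.05 and 0.22 ± 0.11 (adjusted p = 0.843 and 0.383). DNAJA1, a cochaperone gene, stood at 102 FPKM with AGEs and 168 FPKM with BSA (log2 fold change -0.75 ± 0.19, adjusted p = 0.172), and BAG3, which encodes a cochaperone of HSP70, had a log2 fold change of -0.25 ± 0.05 (adjusted p = 0.139).

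The rise of ATF4 targets was followed into genes that had not been looked at before. If the ATF4 program as a whole were higher, cytosolic tRNA synthetases known as ATF4 targets should be higher than the other cytosolic tRNA synthetases. The 12 targets had a median log2 fold change of 0.28 and all were positive, with 10 at an unadjusted p under 0.05 and 0 past the limma adjusted p, and the 8 others had a median of -0.02, a difference of 0.30 (exact two-sided permutation test over genes, which are not independent replicates, p = 0.00557). A response of the endoplasmic reticulum that includes its chaperones would raise those too. However, 15 chaperone and folding enzyme genes outside the list, also not looked at before, had a median of -0.032 (95% order-statistic interval -0.067 to 0.011). The interval is taken over genes, which are not independent replicates, and does not measure the spread between libraries. By limma, 0 of these genes passed the adjusted p, with 1 higher and 1 lower at an unadjusted p under 0.05. These values argue against a common rise of these chaperone genes in these libraries. They do not argue against other parts of the unfolded protein response, which the test did not cover. A hypothesis consistent with these values is that ATF4 activity was higher in the AGEs-treated cells. Its trigger was not tested, and culture conditions that differ between the treatments for other reasons, such as medium depletion, stay open.

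Technical explanations were weighed for the rise of the ATF4 and NF-kB lists. A bias by transcript GC content or length is argued against, since the median of the ATF4 list was 0.61 after correction for both and that of the NF-kB list 0.60, with both lists still past the camera threshold. A few genes taking most of the FPKM is argued against as well, since the 10 most abundant genes took 14.1% of the sum with AGEs and 14.9% with BSA, a difference of -0.733 percentage points. For the count of 26 called genes, the 6 samples can be split in 10 ways, too few for a share under 0.05, and 1 split, the real one, gave as many genes, with 13 in the highest of the others. A difference of depth or of library batch between the treatments could not be tested, because the depth is unknown and no batch is given here.

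Several called genes, among them DPYSL2, TMEM30A, KIAA1191 and PDLIM5, differed by a step with little spread within either group. Reads shared with an overlapping gene on the same strand could give such steps. Of the 26 called genes 23.1% overlapped another annotated gene on the same strand, against 35.0% of the other tested genes (two-sided Fisher's exact test p = 0.225). In the reference annotation 20 had no such overlap, which argues against this source for those, TMEM30A, KIAA1191 and PDLIM5 among them. For the 6 with an overlap (DPYSL2, NFE2L2, IFIT2, IL10RB, Z83844.1 and AC093525.2) it stays open. Overlaps with genes on the opposite strand were not examined. Since the strand setting is not given, reads shared with such genes stay open for all called genes. A change in the transcripts assigned to a gene was not tested, since transcript values were not used here.

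The values of GADD45A and ATF3 differed between the authors' deposited tables by up to 5.37 FPKM. After exchanging both genes in one of the tables, the largest difference over the 12 values was 0, which is consistent with an exchange of names in one table. Which table is right cannot be read from them. With the names exchanged, the log2 fold change of 1.75 would belong to GADD45A and that of 0.98 to ATF3, and both would still have passed. The call that ended in 13 of 18 alternatives would then be that of GADD45A, and the call that ended in 4 that of ATF3.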
